A study of Homo sapiens with 8 samples.

How the data were processed

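PAR-CLIP libraries were made from HAP1 cells that lack their own RBM4 and carry a doxycycline-inducible FLAG-HA-RBM4 transgene, per the labels' protocols. Cells received 100 µM 4-thiouridine for 16 h or 1 h (the labels do not say which library had which time, and no library was assigned to either), were irradiated at 312 nm for 5 min, and RNA was trimmed with RNase T1, recovered with anti-FLAG beads and a gel, and turned into small RNA libraries. Reads were handled with cutadapt 1.8.3 and Bowtie 1.1.2 and placed on hg38 (GRCh38.p5 is also named), per the submitters' processing notes. The caller that made the clusters is not given in the sources used here. One cluster list per library was deposited, so replicates were not pooled.

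Per the file headers, each deposited row gives a cluster's position, strand, annotation class, gene name, sequence, read count, number of conversion positions and number of conversion events as counts, and a T-to-C fraction between 0 and 1. The denominator of the deposited fraction is not stated: multiplied by the read count it was whole, within 0.01, for 49.6% to 79.6% of the clusters of a library. All 155754 clusters had at least 5 reads, at least 2 conversion positions and a length of at least 16 nt, and the span from start to end, both included, equalled the sequence length in 100% of them. A gene with no cluster in a library is therefore unlisted there, and was given no limit from a count of 0. No fold change is given for a gene unlisted in every uninduced library. Where only some libraries listed a gene, the others entered the fit as 0, so its fitted difference depends on the listing minimum. The T-to-C comparison was planned on converted and unconverted counts; as the files give no unconverted counts, the deposited fraction was averaged with read counts as weights instead. Distances to splice sites were planned but not computed, as no genome annotation of this build was used here.

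Each library's depth is the sum of its cluster reads, 141092 to 1988168, and not the number of reads sequenced, which was not used here. These are PCR reads with no molecular identifiers, so counting error understates the error of a value, and the spread over 4 libraries per group is given instead. Groups and replicate numbers came from the sample labels. Annotation classes were those of the files, joined into 13 classes. Of 15334 gene names in the files, 12379 are current symbols in the RefSeq gene table of GRCh38.p14 and 823 were updated from a synonym; others were kept as written. No coordinate was taken from that table. Clusters with no gene name stayed out of gene tests, but their reads counted in the library totals.

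Clusters overlapped when they shared at least 1 nt on the same strand. For the shuffled values, each cluster was moved to a random place within the span of its gene, or of its chromosome when it had no gene. Reproducible regions were merged induced clusters with a cluster in at least 3 of the 4 induced libraries and none in an uninduced library. Single values were compared by exact two-sided permutation tests over the 70 relabellings of 4 against 4, which cannot give a p below 0.0286. Reads in clusters were summed per gene and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with the sum of cluster reads as library size, no scaling factors and filterByExpr's default filter. The SE given with an edgeR log2 difference is its size divided by the square root of the quasi-likelihood F. For the alternative on clusters per gene, genes with clusters in at least 4 libraries and 10 clusters in all were tested. The number of clusters that contain each of the 1024 5-mers was tested in the same way, with the number of clusters as library size and no filter beyond a total of at least 2. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Gene lists were compared by Fisher's exact test. DESeq2 1.42.0 was an alternative for both count tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

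The genes named in the text followed a rule fixed before the data were examined: RBM4 and RBM4B; up to 12 genes with the largest positive and 12 with the largest negative fitted change among those past the threshold with a cluster in all 4 libraries of the higher group (no gene met the negative part); the 12 genes of highest induced read share with a reproducible region; up to 4 genes per list; the 8 regions in all 4 induced libraries with the highest share; and the 10 highest and 5 lowest 5-mers. Some genes, among them genes named by the rule, and the sequence and position of the SPATA6 cluster, are not reported here. SPATA6, NOP56, HSP90AB1, PINX1, UNC5D, the genes lower by clusters per gene and the repeat families were named after their values were seen.

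Alternatives set beforehand were clusters with at least 10 reads, at least 3 conversion positions, other region and overlap rules, TMM factors, DESeq2, no filter on low counts, the number of clusters per gene, intronic clusters alone for 5-mers, the replicate number as a block, and each library left out in turn. Added after seeing the data were the removal of adapter-like and U2-like clusters (a match of at least 14 nt with at most 2 mismatches to the small RNA 5′ adapter or the start of U2 snRNA, or the name U2), the keeping of 1 cluster per sequence on the primary chromosomes, the use of libraries 1 and 2 or 3 and 4 alone, and CG and CGG per 1000 positions with every library weighted to the same GC distribution in bins of 5%. The 5-mer and gene tests were tested on simulated data with the real means and library sizes and 200 changed features. The dispersion was fixed at 0.5 for genes and 0.05 for 5-mers and was not estimated from the libraries, so the recovered shares hold for those settings. Simulated gene counts had no listing minimum, and unchanged genes, adapter-like reads among them, had the same expected share in every library. The false calls given next therefore say nothing about effects of the listing minimum or of adapter-like reads on the real calls. In the simulation of the gene-level test, 53.8% of the 158 tested genes changed 8-fold were recovered among 5745 genes, with 4 false calls of 89; in that of the 5-mer test, all 200 5-mers changed 3-fold were recovered among 1024, with 10 false calls of 210. The overlap, merging, permutation and adjustment functions gave 0 disagreements with direct counting on 200 random sets.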

Results

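The data map where the RNA-binding protein RBM4 was crosslinked to RNA in living human cells. RBM4 is a protein with RNA recognition motifs, known as a regulator of alternative splicing and of translation. The method was PAR-CLIP, in which cells take up 4-thiouridine (4SU), ultraviolet light crosslinks protein to RNA at the thiouridines, and reverse transcription reads a crosslinked thiouridine as C, so that a T-to-C conversion in a read marks contact. The cells were HAP1, a near-haploid human line of leukaemic origin, in which RBM4 had been knocked out and FLAG-HA-tagged RBM4 put under doxycycline control. The 8 libraries fell into 2 groups of 4 biological replicates: 4 from cells given 200 ng/mL doxycycline for 24 h before crosslinking (induced) and 4 from cells given none (uninduced). Each file listed clusters, short stretches of overlapping reads with T-to-C conversions, and no file listed a cluster of under 5 reads or under 2 conversion positions. The cluster reads summed to 878489, 377017, 903852 and 1988168 in induced libraries 1 to 4, and to 141092, 1515937, 1865485 and 1223524 in uninduced libraries 1 to 4.

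The comparison of induced with uninduced cells asks which RNA contacts depend on the presence of tagged RBM4. The RBM4 gene itself was examined first. Clusters at the RBM4 locus, including the overlapping readthrough gene RBM14-RBM4, held 8.40 ± 4.91 of every 10000 cluster reads in induced libraries and 0.722 ± 1.27 in uninduced libraries (SD, n = 4 each). The induced values were 12.9, 10.7, 1.56 and 8.47, and the uninduced values 2.62, 0.178, 0.0858 and 0. The exact two-sided permutation test over the 70 relabellings gave p = 0.0571 for n = 4 against 4. Without induced replicate 3, the only induced library below an uninduced one, the difference was 9.96 and the exact p was 0.0286. With any of the other 7 libraries left out, the exact p was 0.0571 to 0.0857. The shares in uninduced libraries 2 to 4 were lowered by adapter-like clusters, which took 97.5%, 88.3% and 88.6% of their cluster reads. As read counts, the locus had 1135, 402, 141 and 1683 in induced and 37, 27, 16 and 0 in uninduced libraries. Uninduced library 2 held only 38336 reads outside adapter-like clusters, and induced library 3 held 474744. Without adapter-like and U2-like clusters the difference was 8.83 (exact permutation p = 0.0571). A reproducible region lay at chromosome 11, positions 66639889 to 66639913 on the plus strand (hg38), in a part that the files annotate as an intron of RBM14-RBM4, with 76, 11, 0 and 187 reads in induced libraries 1 to 4. The paralog RBM4B had a coding region on the minus strand of chromosome 11, positions 66676867 to 66676902, with 76, 8, 0 and 187 reads. These near-equal counts at both genes leave uncertain which gene such reads came from, and RBM4B had no cluster in any uninduced library. Doxycycline also switches on the RBM4 transgene, whose RNA could give reads placed at these genes. Reads of the transgene were not told apart from those of the genes themselves. The higher share at the RBM4 locus is therefore a check of the labels and does not by itself show a contact there.

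Induced libraries held far more clusters than uninduced libraries. They listed 39561, 21515, 23270 and 59386 clusters, a mean of 35933 ± 17620, against 3147, 1501, 3582 and 3792 in uninduced libraries, a mean of 3006 ± 1038 (SD, n = 4 each). The ratio of geometric means was 11.6, and the exact permutation test of log2 counts gave p = 0.0286 (n = 4 against 4, two-sided), the smallest value this design allows. Cluster reads did not separate the groups, with a log2 difference of 0.07 and an exact permutation p of 0.971. A single cluster in an intron of SPATA6, a spermatogenesis-associated gene, took 90.3%, 87.6% and 87.8% of the cluster reads in uninduced libraries 2, 3 and 4, and 19.9%, 46.8% and 12.2% in induced libraries 2, 3 and 4. Neither library numbered 1 listed it. Its sequence resembles the 5′ adapter of small RNA libraries. Clusters with such adapter-like sequence held 97.5%, 88.3% and 88.6% of the cluster reads in uninduced libraries 2, 3 and 4, and 11.3% in uninduced library 1. In induced libraries 1 to 4 they held 0.832%, 20.7%, 47.5% and 12.7%. The share of cluster reads of every other gene was lowered accordingly. Fits without uninduced library 1 therefore rest on the uninduced libraries where this lowering was largest. Outside clusters with such adapter-like sequence, induced libraries held 871181, 298831, 474744 and 1735355 reads and uninduced libraries 125217, 38336, 217489 and 139965. Counted without adapter-like and U2-like clusters, a choice made after seeing the data, cluster reads were higher in induced libraries by 2.42 on the log2 scale (exact permutation p = 0.0286, n = 4 against 4).

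**Figure D1:**
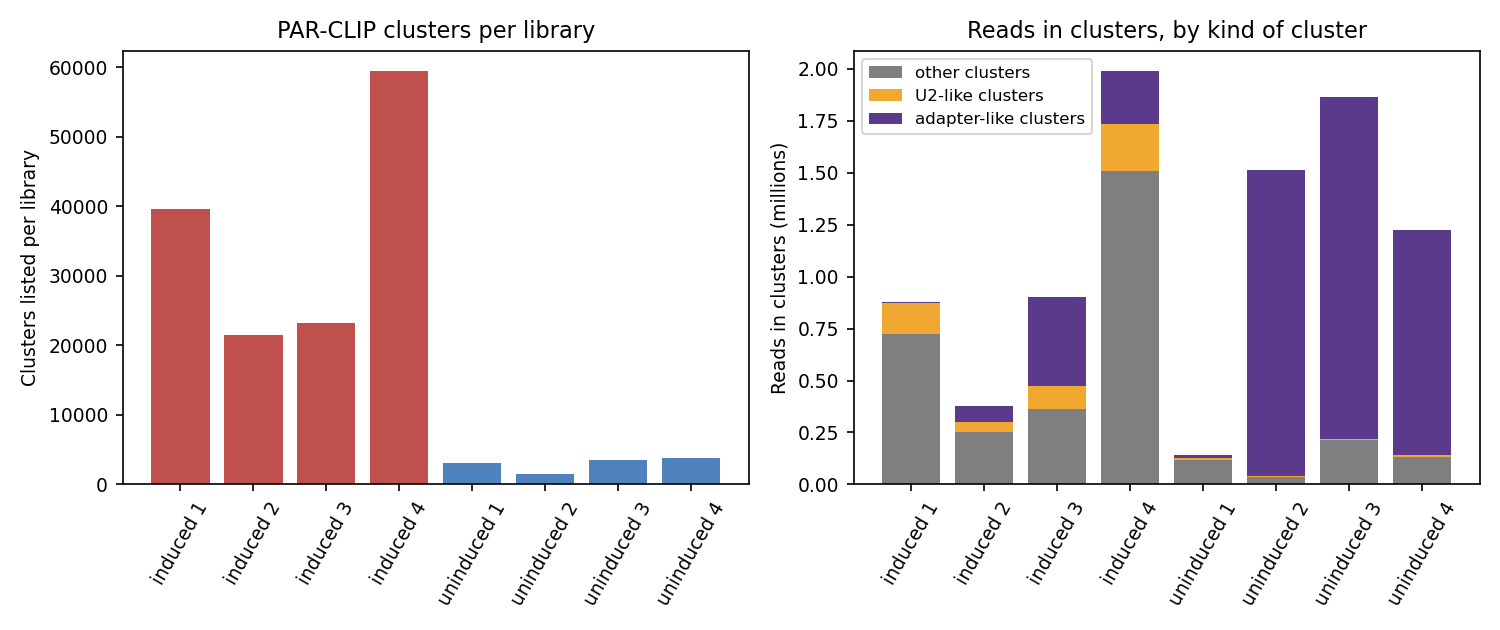
Left, the number of clusters listed in each of the 8 libraries; right, the reads in those clusters, stacked by whether a cluster resembles the small RNA 5′ adapter, resembles the start of U2 snRNA, or neither. The 4 induced libraries lie between 21515 and 59386 clusters and the 4 uninduced libraries between 1501 and 3792, while adapter-like clusters fill most of the reads of uninduced libraries 2 to 4.

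The T-to-C fraction was lower in induced clusters. Weighted by reads, it was 71.6% ± 4.64 in induced and 84.0% ± 5.18 in uninduced libraries (SD, n = 4 each; exact permutation p = 0.0286, two-sided). The difference, induced minus uninduced, was -12.4 percentage points, and -8.77 without adapter-like and U2-like clusters, again with an exact permutation p of 0.0286 (n = 4 against 4). The call ended when 1 cluster per sequence was kept (-9.97, exact p = 0.0571), when at least 3 conversion positions were asked for (-13.3, exact p = 0.0857), by conversion events per 100 reads (-14.8, exact p = 0.143), and with the replicate block, where 4 pairs allow no exact p below 0.125. It also ended when induced library 1, 2, 3 or 4 was left out (differences of -11.4, -10.8, -13.7 and -13.7, exact p = 0.0571 each). All listed clusters had passed a conversion minimum, so the fraction describes listed clusters and not all reads.

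Induced clusters lay mainly in introns. Introns held 51.5% ± 5.95 of the clusters in induced and 34.4% ± 5.26 in uninduced libraries (SD, n = 4 each), and the lowest induced share, 46.3%, lay above the highest uninduced share, 40.1%. Clusters with no annotation made up 24.6% ± 2.44 against 32.4% ± 4.19. Structured small RNAs (snRNA, rRNA, tRNA and the like) made up 0.739% ± 0.377 of induced and 6.54% ± 4.07 of uninduced clusters. The shares of 3′ UTRs were 4.99% ± 2.71 and 4.72% ± 2.42, and those of coding sequence 3.95% ± 2.22 and 5.34% ± 3.51. For introns, unannotated sequence and structured small RNAs the exact permutation p was 0.0286 (n = 4 against 4), and 0.0743 after Benjamini-Hochberg adjustment over the 13 classes, so no class passed the threshold. The intron difference, 17.1 percentage points, was 30.8 among clusters with at least 3 conversion positions (adjusted exact permutation p = 0.124). By reads, structured small RNAs turned round, to 15.2% ± 4.30 in induced and 4.90% ± 8.19 in uninduced libraries (adjusted exact permutation p = 0.212). By reads the intron share turned round as well, to 53.6% ± 13.7 against 73.8% ± 35.1, with the SPATA6 cluster among the uninduced intronic reads; without adapter-like and U2-like clusters it was again higher in induced libraries, by 20.5 percentage points (adjusted exact permutation p = 0.0619).

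**Figure D2:**
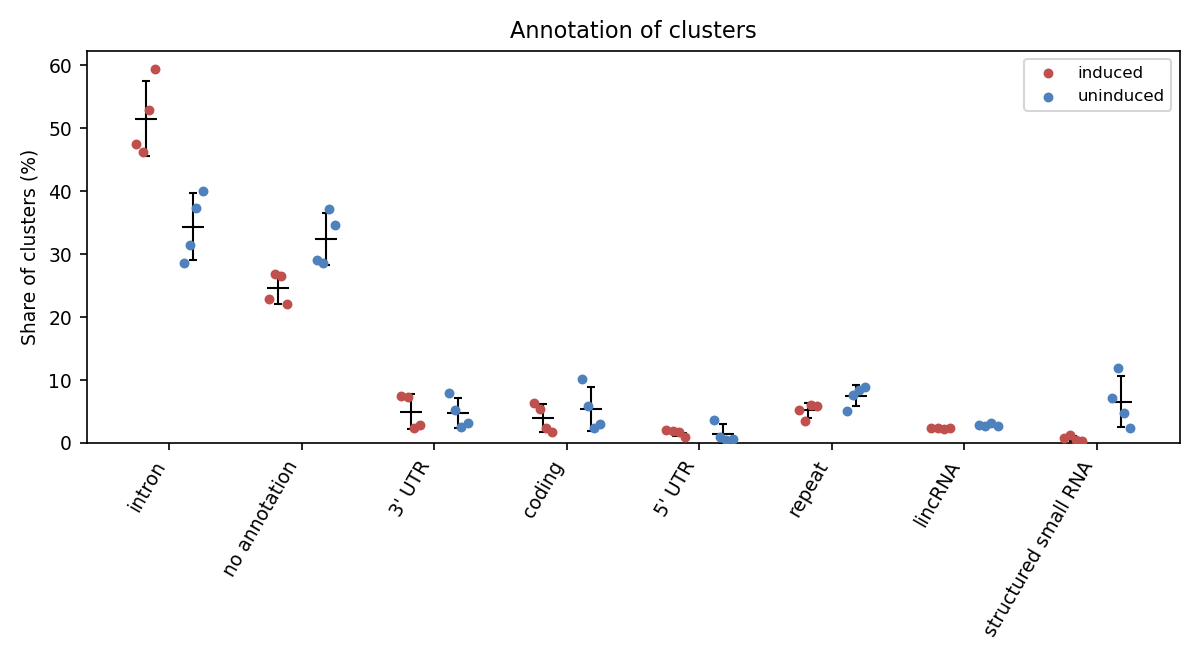
Share of clusters (%) in 8 annotation classes for each library, with the mean and SD of each group of 4 as black bars. The intron shares of the 4 induced libraries lie between 46.3% and 59.3% and those of the uninduced libraries between 28.6% and 40.1%.

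Clusters recurred between induced libraries at specific places. On average 9.37% ± 3.53 of the clusters of an induced library overlapped a cluster of another induced library by at least 1 nt (SD over 12 ordered pairs), against 0.916% after clusters were shuffled. For the 16 pairs of an induced with an uninduced library, whose lists were shorter, the value was 0.774% ± 0.341, against 0.176% after shuffling. Uninduced libraries shared 6.68% ± 2.37 of their clusters with one another (12 ordered pairs), against 1.18% after shuffling. The difference between the 2 groups, 2.70 percentage points, was 0.0963 among clusters with at least 3 conversion positions. An overlap also depends on the length of the other list, 21515 to 59386 clusters in induced and 1501 to 3792 in uninduced libraries. The difference is therefore not a like comparison of how well clusters recurred. Merging the induced clusters gave 128170 regions, of which 2244 held a cluster in at least 3 induced libraries. After removal of the 252 that overlapped an uninduced cluster, 1992 reproducible regions remained, in 1158 named genes, and 264 of them, in 195 genes, held clusters of all 4 induced libraries. The same procedure on shuffled clusters gave 110 regions. Uninduced libraries held only 38336 to 217489 reads outside adapter-like clusters, against 298831 to 1735355 in induced libraries. Many regions could thus have gone unlisted in uninduced libraries for want of reads. A region, or a gene, without an uninduced cluster is therefore not shown to depend on induced RBM4. Introns held 1207 of the reproducible regions (60.6%), unannotated sequence 360, 3′ UTRs 101, repeats 97, coding sequence 50 and 5′ UTRs 29. With induced library 1, 2, 3 or 4 left out, and a cluster in 2 of the other 3 asked for, the number was 6571, 8511, 7932 and 5453. In induced libraries 1 to 4, 27.4%, 33.4%, 37.3% and 29.0% of the clusters shared their sequence with another cluster of the library. In uninduced libraries 1 to 4 it was 25.6%, 20.9%, 19.1% and 17.5%. With 1 cluster per sequence on the primary chromosomes, 1475 regions remained.

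Most of the regions with the highest shares of reads lay in small nuclear RNA annotations. U2 snRNA, which pairs with the branch point in splicing, gave 5 of the 8 highest regions found in all 4 induced libraries. The first, on chromosome 4 at positions 103046353 to 103046382 (plus strand), held 0.291% ± 0.216 of the cluster reads (SD, n = 4). RNVU1-19, a variant U1 snRNA gene, had a region on the minus strand of chromosome 1, positions 120850816 to 120850942, with 0.252% ± 0.174. The other 2 of the 8 resembled U2 in sequence but were annotated as a simple repeat and as unannotated sequence. The U2-like regions are short stretches similar to one another on several chromosomes, so a read can fit more than one of them. The U2 regions on the plus and minus strands of chromosome 13 had the same counts, 177, 105, 606 and 2077 reads. The simple repeat and the unannotated region also shared theirs, 194, 119, 626 and 2114. Such regions hold the same reads listed at more than 1 place and do not count as separate sites. Among regions that the files place in protein-coding genes, listed after their values were seen, RCC1, which regulates chromosome condensation and encodes the exchange factor for Ran, led with an intronic region on chromosome 1, positions 28506518 to 28506571 (plus strand), holding 0.0505% ± 0.0309. Introns of NOP56, a box C/D snoRNP protein, and of HSP90AB1, an HSP90 chaperone, followed with 0.0297% ± 0.0298 and 0.0234% ± 0.0207. An intronic region of HNRNPH1, a G-rich-element-binding splicing regulator, was found in all 4 induced libraries with 121, 48, 237 and 565 reads.

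At the level of genes, many genes held clusters in every induced library and few or none in uninduced libraries. ANKRD11, which encodes a chromatin regulator, held 96.0 ± 31.4 clusters in induced and 1.25 ± 0.50 in uninduced libraries (SD, n = 4 each), with 21 reproducible regions, and its share of reads was higher by 6.33 on the log2 scale (SE 1.75, adjusted p = 0.0134 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call ended with no filter on low counts (edgeR adjusted p = 0.130), with libraries 1 and 2 of each group alone and by clusters per gene (0.458). TBCD, a tubulin-folding cofactor, held 68.3 ± 17.0 against 1.00 ± 1.41 clusters, but its read share did not pass (edgeR adjusted p = 0.121). It passed with DESeq2 (adjusted p = 0.000466), with the replicate block (edgeR adjusted p = 0.0450), with at least 3 conversion positions (0.000200), without uninduced library 1 (0.0107) and in libraries 3 and 4 alone (0.0485). Genes with clusters in all 4 induced and no uninduced library, for which no fold is given, included DAZAP1 with 8.64 ± 7.76 reads per 10000, the adaptor subunit AP2A2 with 5.55 ± 3.27, the RNA-binding protein LARP4B with 5.11 ± 1.71, the elongation factor EEF1A1 with 4.62 ± 3.07, the ubiquitin ligase UBE3A with 4.31 ± 2.84, the Argonaute protein AGO2 with 4.14 ± 1.30, the splicing repressor PTBP1 with 3.39 ± 0.681 and WDR4 with 3.36 ± 1.32 (SD, n = 4). The same rule named RNVU1-19, at 25.2 ± 17.4 reads per 10000, FAM120B, at 15.0 ± 17.0, SMG1P3, at 3.70 ± 1.23, and CCDC200, at 3.52 ± 2.65. RNVU1-19, SMG1P3 and EEF1A1 have near-identical copies elsewhere in the genome, and their reads cannot be assigned to one copy with certainty. Neither FAM120B nor CCDC200 had a reproducible region, and FAM120B held 116 and 147 clusters in induced libraries 1 and 2 but 2 and 6 in libraries 3 and 4.

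Among the genes with the highest read shares and a reproducible region, RCC1 was higher by 6.53 (SE 2.08, edgeR adjusted p = 0.0269) and GNB1, a G protein beta subunit, by 6.16 (SE 1.90, edgeR adjusted p = 0.0234) on the log2 scale. The call for RCC1 ended without induced library 1, 2 or 4 (edgeR adjusted p = 0.0583, 0.0588 and 0.0617), where the difference stayed at 6.40, 6.35 and 6.57. It also ended with TMM factors (4.42, edgeR adjusted p = 0.0857) and without adapter-like and U2-like clusters (3.68, 0.187), among other settings. The call for GNB1 ended without induced library 1 (edgeR adjusted p = 0.0599), among other settings. U2 held 1204 ± 244 reads per 10000 in induced and 131 ± 215 in uninduced libraries (SD, n = 4 each), with a log2 difference of 3.20 (SE 1.88) that did not pass (edgeR adjusted p = 0.191). Uninduced library 1 held 452 reads per 10000. Adapter-like clusters took 11.3% of its cluster reads, against 97.5%, 88.3% and 88.6% in uninduced libraries 2 to 4. Outside adapter-like clusters the U2-like share was 6.25%, 3.27%, 2.21% and 4.70% in uninduced libraries 1 to 4. Without uninduced library 1 the U2 difference was 5.65 and passed (edgeR adjusted p = 0.0280), in a fit that rests on the libraries with most adapter-like reads. It also passed with DESeq2 (3.47, adjusted p = 4.29e-07), with the replicate block (edgeR adjusted p = 0.0421) and in libraries 3 and 4 alone (0.0329). RN7SK, the 7SK RNA that controls transcription elongation, gave 2.36 (SE 1.51, edgeR adjusted p = 0.225), XPO1 2.41 (SE 1.78, edgeR adjusted p = 0.287), HNRNPC 1.35 (SE 2.23, edgeR adjusted p = 0.625) and the large-subunit ribosomal RNA repeat 0.45 (SE 1.47, edgeR adjusted p = 0.805). HNRNPA2B1 gave 5.30 (SE 1.98) and narrowly missed the threshold (edgeR adjusted p = 0.0522). HNRNPA2B1 passed with DESeq2 (adjusted p = 0.000148), with the replicate block (edgeR adjusted p = 0.0477), with at least 3 conversion positions (0.0209) and without uninduced library 1 (0.0184) or 3 (0.0380). Without uninduced library 1, XPO1 (4.43, edgeR adjusted p = 0.0468) and HNRNPC (6.005, edgeR adjusted p = 0.0314) passed as well.

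In all, 1597 of 3447 tested genes had a higher share of cluster reads in induced libraries and 0 a lower one by edgeR (1829 and 0 at an unadjusted p under 0.05), while DESeq2 gave 1703 and 10. Of the 1597, 1264 had no cluster in any uninduced library. Their tests rest on files that list nothing below 5 reads. The median over all tested genes was itself 4.31 on the log2 scale. Both the count and the median differed under other choices, each of which also changed the genes tested: without adapter-like and U2-like clusters 566 genes were higher and 2, PINX1 and UNC5D, were lower of 2163 tested, with a median of 1.99, and when clusters per gene, in place of reads, were tested against all clusters of a library 0 were higher and 14 lower of 2896 (166 and 77 at an unadjusted p under 0.05). Leaving out uninduced library 1, 2, 3 or 4 gave 3874, 3005, 3255 and 3355 genes.

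**Figure D3:**
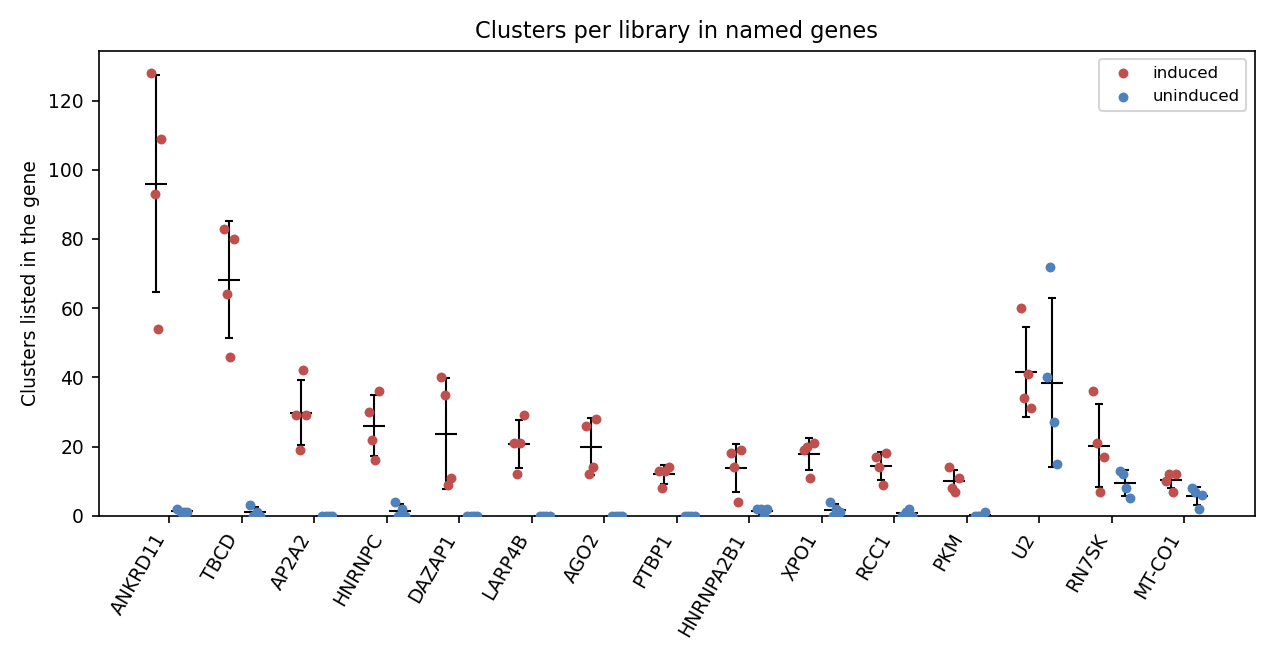
Number of clusters listed in each library for 15 named genes, with the mean and SD of each group of 4 as black bars. ANKRD11 had 54 to 128 clusters in the induced and 1 or 2 in the uninduced libraries, whereas U2, RN7SK and MT-CO1 had clusters in all 8 libraries.

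The 19 gene lists fixed before the data were examined were compared by the share of members with a reproducible region, among genes with a cluster in any library, where 7.5% to 7.6% of other genes had one. This background was not matched for RNA abundance or gene length. Every list with a region had a higher share than other genes, with odds ratios from 1.11 for abundant structured RNAs to 10.8 for SR proteins. A higher share is therefore no sign by itself of a preference of RBM4 for a list. SR proteins, hnRNP proteins and mitochondrially encoded RNAs had the highest shares. Of 15 SR proteins with a cluster, which promote exon inclusion, 7 had a region (46.7%, Fisher's exact test, adjusted p = 0.000328), among them SRRM2, SRSF1, TRA2A and SRSF7. Of 24 hnRNP genes, 10 had one (41.7%, adjusted p = 8.17e-05 by Fisher's exact test), including HNRNPA2B1, HNRNPC, HNRNPH1 and HNRNPD. SRSF1 and SRSF7 had clusters in all 4 induced and no uninduced library, with 2.94 ± 2.53 and 2.23 ± 1.07 reads per 10000 (SD, n = 4). Introns of SRSF7 on chromosome 2, positions 38750692 to 38750768 (minus strand), gave 73, 23, 72 and 370 reads. At gene level 5 of 11 tested SR genes and 7 of 21 tested hnRNP genes passed over all genes, and 5 and 6 adjusted over the list alone, against 1597 of 3447 among all tested genes.

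Genes known as targets of RBM4 in splicing and translation followed, with regions in 5 of 15 members (33.3%, Fisher's exact test, adjusted p = 0.0122), a call that ended with genes in at least 2 libraries as background (adjusted p = 0.0792). PKM, which encodes pyruvate kinase isoforms made by mutually exclusive exons, had 3 reproducible regions and a read share higher by 8.08 on the log2 scale (SE 2.10, edgeR adjusted p = 0.00982). The fit rests on 1 uninduced library with 9 reads, and by clusters per gene the difference was 1.73 and did not pass (edgeR adjusted p = 0.458). The strongest PKM region lay in an intron on chromosome 15, positions 72230775 to 72230820 (minus strand), with 57, 0, 326 and 618 reads. PTBP1 had a region across an exon-intron boundary on chromosome 19, positions 807883 to 807913 (plus strand), with 88, 18, 77 and 487 reads. PTBP2 and FGFR2 had regions as well, while their read shares, with log2 differences of 4.12 (SE 1.67, edgeR adjusted p = 0.0705) and 2.17 (SE 1.52, edgeR adjusted p = 0.265), did not pass. PTBP2 passed with DESeq2 (adjusted p = 0.00375), with at least 3 conversion positions (edgeR adjusted p = 0.0190) and without uninduced library 1 (0.0250) or 2 (0.0485). Adjusted over the list alone, 5 of 9 tested members passed, as they did over all genes.

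Further lists with more regions than other genes were chromatin regulators (10 of 46, adjusted p = 0.00921), translation factors (9 of 41, 0.0114), core spliceosome components (7 of 35, 0.0302), the microRNA machinery (4 of 13, 0.0302) and nuclear long non-coding RNAs (4 of 13, 0.0302), all by Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists. The spliceosome call ended with at least 10 reads (3 of 33, adjusted p = 0.590), with 1 cluster per sequence (0.0863), in all 4 induced libraries (0 of 35, 1) and without induced library 1 (0.113). That of nuclear long non-coding RNAs ended without induced library 1 (adjusted p = 0.333) or 2 (0.116), with regions in at least 2 induced libraries (0.0747) and in all 4 (0 of 13, 1). The microRNA call ended without induced library 3 (adjusted p = 0.0601), and that of chromatin regulators with regions in all 4 induced libraries (0 of 46, 1). The translation initiation factor EIF4A1 and the decay factor UPF1 had no uninduced cluster and 2.64 ± 1.31 and 3.28 ± 2.67 reads per 10000 (SD, n = 4), although the decay list as a whole did not pass, with 2 of 14 members. Mitochondrially encoded RNAs had regions in 7 of 15 members (adjusted p = 0.000328, Fisher's exact test), but in 3 of 14 when 1 cluster per sequence was kept (adjusted p = 0.147), and 0 of 14 tested members were higher at gene level by edgeR. MT-CO1 held 5.53 ± 3.46 reads per 10000 in induced and 5.84 ± 8.52 in uninduced libraries (SD, n = 4 each). Uninduced library 1 held 18.6, but adapter-like clusters took 97.5%, 88.3% and 88.6% of the reads of uninduced libraries 2 to 4 and 11.3% of its own. As read counts, MT-CO1 had 262, 185, 167 and 327 in uninduced libraries 1 to 4. The log2 difference of -0.08 for MT-CO1 became 1.79 without uninduced library 1 (edgeR adjusted p = 0.185), a shift that goes with these adapter-like reads. Cytosolic ribosomal protein genes (8 of 77, adjusted p = 0.483), cell cycle (6 of 35, 0.0716), DNA repair (6 of 33, 0.0666), Hippo pathway (4 of 18, 0.0716), circadian clock (3 of 13, 0.102), mTOR and insulin signalling (3 of 24, 0.502), apoptosis (2 of 23, 0.730), abundant structured RNAs (1 of 12, 0.683) and blood lineage markers (0 of 3, 1) did not pass Fisher's exact test. With regions in at least 2 induced libraries, ribosomal protein genes (adjusted p = 3.19e-05), Hippo pathway (0.000647), mTOR and insulin signalling (0.00625), cell cycle (0.0244) and the decay list (0.0486) passed that test. Ribosomal protein genes also passed it without induced library 1, 2, 3 or 4 (0.000126, 0.00144, 0.0206 and 0.00140). DNA repair passed without induced library 2 (0.0334) or 3 (0.0208), and circadian clock without induced library 4 (0.0171). Hippo pathway passed Fisher's exact test without induced library 1, 2 or 4 (adjusted p = 0.00159, 0.000102 and 0.000539). So did mTOR and insulin signalling without induced library 2, 3 or 4 (0.00991, 0.0208 and 0.00561), and the decay list without 2 or 3 (0.0400 and 0.0320). Cell cycle passed without induced library 1 (0.0231) and with at least 10 reads (0.0405). With the background limited to genes with clusters in at least 2 libraries, of which 11.5% had a region, SR proteins (adjusted p = 0.00473), hnRNP proteins (0.00329) and mitochondrial RNAs (0.00473) still passed the exact test, and the known RBM4 targets (0.0792) and the 5 other lists above did not.

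The sequences of induced clusters were rich in 5-mers with CG, above all with CGG. TCGGT occurred in 7.09% ± 1.35 of the clusters of induced libraries and 0.834% ± 0.166 of those of uninduced libraries (SD, n = 4 each), a log2 difference of 3.06 (SE 0.27, edgeR adjusted p = 3.64e-05). The overlapping 5-mers TTCGG (6.60% ± 1.82 against 0.946% ± 0.317), CGGTC (3.77% ± 0.811 against 0.447% ± 0.457) and CGGTA (2.60% ± 0.796 against 0.324% ± 0.112) were higher with it. In libraries 1 and 2 alone CGGTC did not pass (edgeR adjusted p = 0.0795). CCGGG, which did not pass there (edgeR adjusted p = 0.0908) or with at least 3 conversion positions (0.144), reached 8.66% ± 2.98 against 1.37% ± 1.25, GGCGG 4.75% ± 0.988 against 0.779% ± 0.339, and ACGGG, with the largest fitted difference of 3.46 (SE 0.54, edgeR adjusted p = 0.000424), 2.64% ± 1.90 against 0.231% ± 0.131. CGCGT, ACACG and ACTCG completed the 10 highest. The 5-mers with the largest differences in the other direction were TTGAA (0.279% ± 0.0243 in induced and 2.79% ± 0.774 in uninduced clusters), AAGAT, TAAGA, TTGAT and ATTGA.

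In all, 196 of all 5-mers were more frequent and 251 less frequent in induced clusters (edgeR, Benjamini-Hochberg adjusted). Of the 48 that contain CGG, 46 were higher and 0 lower, and of the 244 that contain CG, 141 were higher and 9 lower. Mean GC content was 50.3%, 50.7%, 55.2% and 44.9% in the clusters of induced libraries 1 to 4 and 50.5%, 40.1%, 39.7% and 41.4% in those of uninduced libraries 1 to 4. With all libraries weighted to one GC distribution, a test added after seeing the data, the difference in CGG per 1000 positions fell from 19.7 to 12.4 and that in CG from 34.5 to 19.3, each with an exact permutation p of 0.0286 (n = 4 against 4). Part of both differences therefore went with GC content. In intronic clusters alone TCGGT differed by 3.16 and CGGTC by 3.89 on the log2 scale. Of the motifs fixed before the data were examined, the CG-rich RBM4 motif GCGCG or CGCGC occurred in 3.14% ± 0.888 of induced and 1.01% ± 0.893 of uninduced clusters (SD, n = 4 each; adjusted exact permutation p = 0.129 over 3 motifs), CTCTC or TCTCT in 12.7% ± 2.22 and 9.17% ± 1.53 (adjusted exact permutation p = 0.129), and TTTTT in 8.19% ± 2.18 and 9.30% ± 2.61 (adjusted exact permutation p = 0.486). As single 5-mers, GCGCG passed with a log2 difference of 1.84 (SE 0.58, edgeR adjusted p = 0.0230) and CGCGC did not, with 1.09 (SE 0.57, edgeR adjusted p = 0.145); in intronic clusters alone both passed, with 3.91 (edgeR adjusted p = 0.000295) and 2.64 (edgeR adjusted p = 0.0045). GCGGC differed by 2.23 (SE 0.33, edgeR adjusted p = 0.000312) and CGGCG by 1.82 (SE 0.49, edgeR adjusted p = 0.00998). The call for GCGCG ended without induced library 1 (edgeR adjusted p = 0.0582), without uninduced library 3 (a difference of 1.649), with at least 3 conversion positions (0.422) and in libraries 1 and 2 alone (0.204). That for CGGCG ended with at least 3 conversion positions (edgeR adjusted p = 0.0727) and in libraries 1 and 2 alone (0.160). CGCGC passed without uninduced library 1 (edgeR adjusted p = 0.00590) and with 1 cluster per sequence (0.00668). CTCTC, with 0.61 (SE 0.28, edgeR adjusted p = 0.0967), TCTCT, with 0.32 (SE 0.23, edgeR adjusted p = 0.286), and TTTTT, with -0.18 (SE 0.28, edgeR adjusted p = 0.637), did not pass. CTCTC passed with DESeq2 (adjusted p = 0.0369), with at least 10 reads (edgeR adjusted p = 0.0433), with 1 cluster per sequence (0.0119), without uninduced library 1 (0.00850) and in libraries 3 and 4 alone (0.0322). The counts of 5-mers fell to 62 and 81 with libraries 1 and 2 of each group alone, and to 87 and 155 among clusters with at least 3 conversion positions.

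**Figure D4:**
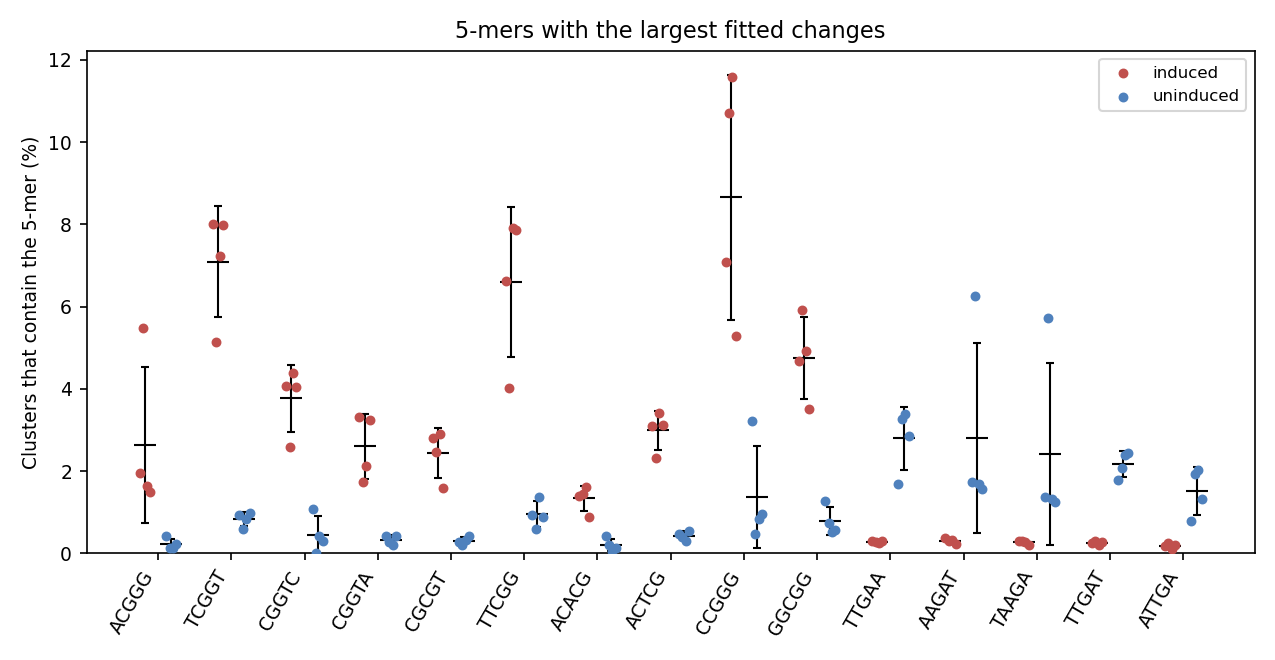
Percentage of clusters that contain each of the 10 5-mers with the largest positive and the 5 with the largest negative fitted differences, for each library, with the mean and SD of each group of 4 as black bars. TCGGT lies between 5.14% and 8.0% in the induced and between 0.600% and 0.976% in the uninduced libraries.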

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

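The tests of the SPATA6 and U2-like patterns, of other splits of the libraries and of repeat families were chosen after the results were seen, and those of the TCGGT pattern before theirs. Chance flags about 1 in 20 groups of 4, and many of the values below come from a single library, uninduced library 1, the only uninduced library without the SPATA6 cluster and with the lowest total.

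In uninduced library 1, reads per 10000 cluster reads lay far above the other 3 uninduced libraries for RBM4 and the RBM4 locus (2.62 for both), U2 (452), ANKRD11 (1.42), RN7SK (21.0), the large-subunit ribosomal RNA repeat (35.2), XPO1 (5.46), EIF4G3 (1.13), MT-CO1 (18.6), MT-ND4 (14.4) and MT-CYB (4.89), and far below them for SPATA6 (0). Adapter-like clusters held 97.5%, 88.3% and 88.6% of the reads of uninduced libraries 2 to 4 and 11.3% of library 1. Shares of all other genes were thereby lowered in libraries 2 to 4, so these gaps say little about library 1 itself. As read counts, MT-CO1 had 262, 185, 167 and 327, and RN7SK 296, 592, 486 and 235, in uninduced libraries 1 to 4. Among induced libraries, library 1 stood apart with 1570 for U2 and 18.5 for GNB1, library 2 with 0.159 for PDPK1, library 3 with 0.199 for U2AF2, 0.277 for RPS23 and 0.786 for XRCC5, and library 4 with 0.379% of its clusters in the class of all other annotations.

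The SPATA6 cluster is the first pattern. Over a stretch of 19 nt with 2 mismatches its sequence matched the small RNA 5′ adapter, while 10000 shuffles of the same bases reached at most 15 nt. Reads of the adapter may therefore account for it. Binding of induced RBM4 there is argued against by the 87.6% to 90.3% of reads it held in 3 libraries without doxycycline, above the highest induced share of 46.8%. The mean difference, induced minus uninduced, was -46.7 percentage points (19.7% ± 19.8 against 66.4% ± 44.3, SD, n = 4 each), which did not pass the exact permutation test (p = 0.143). Why libraries 1 of both groups lack it was not tested.

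U2-like clusters are the second. They held 17.1% ± 4.67 of the reads outside adapter-like clusters in induced and 4.11% ± 1.76 in uninduced libraries (SD, n = 4 each; exact permutation p = 0.0286), and the lowest induced share lay 6.86 percentage points above the highest uninduced one. This restates the pattern, so whether more U2 was recovered with induced RBM4 remains open. Many of these clusters are imperfect copies of U2, and T in the copy against C in U2 made up 44.9% of their differences from U2, weighted by reads, ahead of A against G with 31.8%. Whether apparent conversions there are such mismatches cannot be told apart from crosslinking, since this share lies between the bounds set for either reading and each cluster had to show conversions to be listed.

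TCGGT in induced clusters is the third. Its frequency was 3.40 ± 0.719 per 1000 positions in induced and 0.480 ± 0.137 in uninduced clusters (SD, n = 4 each). A difference in GC content is argued against, because with all libraries weighted to one GC distribution the induced mean was still 6.35 times the uninduced mean. The ratio was 9.89 among the 1000 clusters of highest read count in each library, taken after adapter-like and U2-like clusters were removed. The difference was therefore not confined to the additional clusters of low read count in induced libraries. Those 1000 are most of the 1501 clusters of uninduced library 2 but few of the 59386 of induced library 4. In induced library 4 the frequency was 4.08 in all clusters and 13.2 in these 1000. Libraries were thus not matched in depth, and a part of depth in the difference cannot be told from this ratio. As binding by induced RBM4 would have it, TCGGT was more frequent in reproducible regions than in clusters of one library alone in all 4 induced libraries, by 3.16 to 7.37 times. Overlap with uninduced clusters, which held less TCGGT, had removed 252 of 2244 regions from the first set, and nothing from the second. This removal could itself have raised the ratios, by an amount not computed. Binding by induced RBM4 at TCGGT remains a hypothesis, since the pattern was found in the same libraries. A role of sequence preferences of RNase T1 or of crosslinking in the presence of the protein was not tested.

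Chance in the grouping of libraries was looked at with the 35 splits of the 8 libraries into 4 and 4. For genes 1 split, the real one, gave as many as 1597, and the highest of the others gave 1. For 5-mers 1 split, again the real one, gave as many as 447, and the highest of the others gave 0. No lower share than 1 of 35 was possible, and every other split mixes induced with uninduced libraries. The groups as a whole therefore differed, while no single gene or 5-mer is borne out by this count.

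Clusters in Alu repeats, outside the main comparisons, made up a larger share of the induced than of the uninduced clusters. Per 1000 clusters, induced libraries held on average 2.78 clusters in AluY, 1.93 in AluSx1, 1.59 in AluSx, 1.38 in AluSz, 1.36 in AluSq2 and 1.21 in AluSp, and uninduced libraries 0.442, 0.452, 0.236, 0.517, 0.0659 and 0. For each the exact permutation p was 0.0286 (n = 4 against 4), and 0.0408 after adjustment over the 10 families looked at. That adjustment does not cover the choice of the families, which followed their values. A sequence listed at several places counts at each of them, and these shares were not computed with 1 cluster per sequence.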

How the results depend on the processing

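The removal of adapter-like and U2-like clusters, the keeping of 1 cluster per sequence, libraries 1 and 2 or 3 and 4 alone, conversion events per 100 reads, and one GC distribution for CG and CGG were chosen after seeing the data; other alternatives were set before. The cause was not tested unless given. Exact tests of 4 against 4 and cluster lists with a minimum of 5 reads limit what can be detected. The distance to splice sites was not run, for want of an annotation of this build.

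Cluster reads per library, 0.07 on the log2 scale, became -0.0959 with at least 10 reads, -0.329 with at least 3 conversion positions, -0.0805 with 1 cluster per sequence, 2.42 without adapter-like and U2-like clusters, and -0.784 to 0.478 with 1 library left out. The T-to-C difference, -12.4, no longer passed at -13.3 with at least 3 conversion positions, -9.97 with 1 cluster per sequence and -14.8 by events per 100 reads, and ranged from -14.8 to -10.8 with 1 library left out. The intron difference, 17.1, was 30.8 with at least 3 conversion positions and -20.2 by reads. The difference in replicate overlap, 2.70, was 0.0963 with at least 3 conversion positions. At one GC distribution the CG difference went from 34.5 to 19.3 per 1000 positions and the CGG difference from 19.7 to 12.4. The RBM4 locus difference ranged from 6.17 to 9.96 with 1 library left out. Reproducible regions numbered 1198 with at least 10 reads, 758 with at least 3 conversion positions, 1475 with 1 cluster per sequence, and 12253 in at least 2 and 264 in all 4 induced libraries. They numbered 1999 to 8511 with 1 library left out, where fewer libraries were required if an induced one was missing. With genes in at least 2 libraries as background, 3 gene lists passed instead of 9. The number was 13 with regions in at least 2 induced libraries, 6 in all 4, and 7 with 1 cluster per sequence. Without induced library 1, 2, 3 or 4 it was 10, 13, 12 and 13.

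Genes higher and lower numbered 1333 and 0 with TMM factors, 1703 and 10 with DESeq2, 3314 and 93 with no filter, 1030 and 0 with at least 10 reads, 803 and 0 with at least 3 conversion positions, 566 and 2 without adapter-like and U2-like clusters, 1496 and 0 with 1 cluster per sequence, 2741 and 4 in libraries 1 and 2, 3374 and 22 in libraries 3 and 4, 0 and 14 by clusters per gene, and 1496 to 3874 and 0 to 2 with 1 library left out. The median over genes tested in both moved by -0.76 with TMM factors, -2.10 with DESeq2, -1.52 without adapter-like and U2-like clusters and -4.13 by clusters per gene. The 5-mers higher and lower numbered 62 and 81 in libraries 1 and 2, and 87 and 155 with at least 3 conversion positions.

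By the check made, replicate numbers did not clearly pair the libraries. Deviations of same-numbered libraries correlated at 0.126, 0.0476, 0.00157 and 0.0665 over genes, and those of differently numbered libraries at -0.121 to 0.107. Over 5-mers the values were -0.146, 0.0883, -0.291 and 0.241 for the same number, and -0.571 to 0.482 for different numbers. Libraries 1 of both groups lacked the SPATA6 cluster, so a batch shared by replicate number is left open. With the replicate block, the difference in clusters per library of 3.54 and in T-to-C of -12.4 did not pass, as 4 pairs allow no p below 0.125; 1234 genes were higher and 0 lower, 187 and 237 5-mers differed, and MT-CO1 was 0.92.

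Among the genes that the rule names, 1218 values kept direction and side of the threshold, 109 passed it newly, 64 no longer passed and 38 changed sign; of the named 5-mers, 357, 8, 9 and 0. Of the 64, 36 were lost by clusters per gene, among them ANKRD11, RCC1, GNB1, PKM, PTBP1, DAZAP1 and AGO2. The others included CREBBP with DESeq2, TMM factors, at least 10 reads, libraries 3 and 4, no adapter-like or U2-like clusters, and each induced library left out; RCC1 with TMM factors, no filter, libraries 3 and 4, no adapter-like or U2-like clusters, and without induced library 1, 2 or 4; GNB1 with no filter, libraries 1 and 2, and without induced library 1; ANKRD11 with no filter and libraries 1 and 2; RNVU1-19 with libraries 1 and 2; EIF4E and STK3 with libraries 3 and 4; STK3 with the block; and RBM14-RBM4 and EIF4E without adapter-like and U2-like clusters. The 5-mers lost were CCGGG, GCGCG and CGGCG with at least 3 conversion positions, these and CGGTC with libraries 1 and 2, and GCGCG without induced library 1 or uninduced library 3. U2, 3.20, passed at 5.65 without uninduced library 1. Signs changed for MT-ND4 (-0.269) and MT-ND2 (-0.787) with TMM factors; MT-ND4 (-0.263) and MT-ND2 (-0.398) with DESeq2; LSU-rRNA_Hsa (-2.282), MT-ND4 (-0.076) and MT-ND2 (-0.019) in libraries 1 and 2; MT-CO1 in libraries 3 and 4 (0.964), with at least 10 reads (0.175) and at least 3 conversion positions (0.253). Without adapter-like and U2-like clusters they changed for RN7SK (-0.155), LSU-rRNA_Hsa (-0.472), MT-ND4 (-0.635) and MT-ND2 (-1.578), and with 1 cluster per sequence for MT-ND2 (-2.134). By clusters per gene they changed for RBM4 (-0.219), U2 (-3.712), RN7SK (-2.544), HNRNPA2B1 (-0.369), LSU-rRNA_Hsa (-2.911), XPO1 (-0.111), TRA2A (-0.13), E2F3 (-0.157), MCM2 (-0.922), NF2 (-1.322), MT-ND4 (-2.471), MT-CYB (-1.887), MT-ND2 (-2.447) and NEAT1 (-0.362). With 1 library left out, LSU-rRNA_Hsa ranged from -0.205 to 2.356, MT-CO1 from -0.589 to 1.793 and MT-ND4 from -0.256 to 2.478.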

Other observations

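The test of clusters per gene was set before the data were examined, and the repeat families were chosen and tested after their values were seen. The RNAs that took a larger share of clusters in uninduced than in induced libraries included several non-coding and mitochondrial RNAs. When clusters per gene were tested against all clusters of a library, 14 genes were lower in induced libraries by edgeR with Benjamini-Hochberg adjustment. They included the mitochondrial ribosomal RNAs MT-RNR1, by a log2 difference of -3.68 (SE 0.67, adjusted p = 6.48e-05), and MT-RNR2, with -3.40 (SE 0.62, adjusted p = 6.48e-05), the 5S ribosomal RNA, with -2.93 (SE 0.63, adjusted p = 0.00223), the U3 small nucleolar RNA, with -4.29 (SE 0.82, adjusted p = 0.000142), RMRP, with -3.41 (SE 0.87, adjusted p = 0.0229), and the Y RNA RNY3, with -3.26 (SE 0.78, adjusted p = 0.00896). MT-CO1, MT-CO2, MT-ND2 and MT-ND4 were lower as well, with log2 differences from -2.45 (MT-ND2) to -2.77 (MT-CO2). By reads against all cluster reads MT-CO1 differed by -0.08 (SE 1.31, edgeR adjusted p = 0.961), and by 1.79 without uninduced library 1. MT-CO1 had 10, 12, 7 and 12 clusters in induced and 8, 7, 2 and 6 in uninduced libraries. MT-ND4 had a mean of 7.75 clusters in induced and 4 in uninduced libraries, and MT-ND2 6.25 and 3. Their numbers of clusters were thus higher in induced libraries, while the total number of clusters rose more, so their shares were lower.

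Endogenous retrovirus sequences differed between induced libraries. HERVH-int, the internal part of the HERV-H family, held 12, 5, 225 and 732 clusters in induced libraries 1 to 4 and 0, 1, 0 and 1 in uninduced libraries. LTR5_Hs held 19, 35, 82 and 62 clusters in induced libraries and 2 in all uninduced libraries together. A sequence listed at several places counts each time in these numbers, which were not repeated with 1 cluster per sequence. L2a, an old LINE, held 78, 21, 32 and 115 clusters in induced and 10, 6, 11 and 12 in uninduced libraries, so its number was higher in induced libraries while its share of all clusters was lower, with 1.56 ± 0.478 per 1000 induced and 3.35 ± 0.432 per 1000 uninduced clusters (SD, n = 4 each; exact permutation p = 0.0286). Shares of coding sequence and 3′ UTR also differed within groups: coding sequence held 6.31%, 5.37%, 2.38% and 1.76% of the clusters of induced libraries 1 to 4, and 10.1%, 5.86%, 2.43% and 2.98% of those of uninduced libraries 1 to 4. The labels name 16 h and 1 h of labelling without assigning either to a library, so no test was made of that difference.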
